A study of Rattus norvegicus with 19 samples.

How the data were processed

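Liver RNA of Wistar Han rats was measured on 19 Affymetrix Rat230_2 arrays, which carry 31099 probe sets. Per the labels, dams received corn oil or DE-71, a commercial mixture of pentabromodiphenyl ethers used as a flame retardant, by gavage from gestation day 6 to postnatal day 4. The dose was 0, 0.1, 15 or 50 mg/kg per day, with 5, 5, 4 and 5 arrays in that order. Per the labels, 100 ng of RNA from the left lateral lobe was amplified with the 3' IVT Plus kit. The deposited values are log2 signals, and the submitters' processing notes name RMA (robust multi-array average), a background correction, quantile normalization and summary of the probes of a probe set. Its version is not given in the sources used here. RMA compresses folds at both ends of the signal range, and transcripts close to the top of the range, such as Cyp1a1 at 50 mg/kg, can read too low a fold. Array medians lay between 6.05 and 6.16, and single values between 2.395 and 15.06. The precision of each comparison is limited by the number of arrays.

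From the deposited log2 values, 57 control probe sets were left out and 31042 were tested. The platform annotation gave 20826 of them 1 gene symbol, 436 several and 9780 none. Of those with 1 symbol, 20758 matched a RefSeq gene table by gene ID and took its symbol. A gene stands for its probe set with the highest mean over all 19 arrays, which gave 14217 genes. No gene was named from a probe set with several symbols.

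The submitters compared vehicle with each dose in R/maanova at a false discovery rate of 0.05. That package was not used here. The same model of 1 mean per dose group was fitted with limma 3.58.1 in R 4.3.3 over all 19 arrays, with a shared estimate of the spread (15 residual degrees of freedom and 2.78 prior degrees of freedom). Adjusted p-values are limma's two-sided moderated test with Benjamini-Hochberg adjustment over all probe sets of a comparison, and 0.05 was the threshold. A comparison of 50 with 15 mg/kg was added to those of the submitters. Fold changes are differences of mean log2 values, given with limma's standard error (SE).

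Gene lists were 25 pathway lists and 12 cell type lists, of which 36 had at least 5 measured members. They were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over 108 tests (36 lists and 3 doses). Each call is given with the adjusted p that camera gives with an estimated correlation. Counts of members that passed are given over all probe sets and adjusted over the list alone. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per comparison, the 12 largest rises and the 12 largest falls among genes that passed and whose groups did not overlap, or the 5 smallest unadjusted p-values where fewer than 5 genes passed. It also named up to 4 members per list with the largest change at 50 mg/kg, the called members of cell type lists, and Cyp1a1, Cyp3a members, Cyp7a1, Afp, Ttr and Dio1. Cyp2b1, Cyp2b2 and Ugt1a members were also in the rule, but no probe set with 1 symbol stood for them, so they were not analysed here by name. Lists of kidney, intestine and eosinophil transcripts were added after the values had been seen.

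The fit was tested on simulated data for all 31042 probe sets. At the group sizes of 50 mg/kg against vehicle it recovered 64.2%, 88.1% and 95.5% of the probe sets moved by 0.5, 1 and 2 on the log2 scale, with 4.07% false calls. In the same test for 15 mg/kg the recovered shares were 55.2%, 82.1% and 95.5%. Each share rests on 66 or 67 moved probe sets. The simulated noise was normal and independent between probe sets and arrays. Real arrays can share shifts, so the shares recovered and the false calls need not hold for these data.

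The alternatives were a filter at the median level, a variance prior with trend and robust settings, an ordinary t without shrinkage, fits of the compared groups alone, a replicate block, the array number as a covariate, arrays centred on their medians, cyclic loess, array weights, an estimated correlation, the mean of all probe sets of a gene, and each array left out in turn. Chosen after the data had been seen were fits without the doubted arrays, with scores of other tissues as covariates, and with early and late arrays as a block. The simulated overlap of calls between groups that share their control arrays and the count of non-overlapping groups over all genes were also chosen then. Each array's description holds a different 4-digit number, which the labels do not explain. They do not say that the arrays of a group come from separate animals or litters, so p-values measure the spread between these samples.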

Results

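The data were liver transcript levels on postnatal day 4 after gavage of dams with DE-71 at 0, 0.1, 15 or 50 mg/kg per day, with 5, 5, 4 and 5 arrays. The fetal and early postnatal proteins alpha-fetoprotein (Afp, 14.61 ± 0.0511) and insulin-like growth factor 2 (Igf2, 13.86 ± 0.13) stood near the top of the log2 range (mean ± SD, n = 19 arrays). The labels do not say whether the livers are of pups or of the dosed dams, and give the sex as female without saying of which animal. The Y-linked transcripts Eif2s3y (9.55 to 10.07) and Uty (9.46 to 10.03) were high on all 19 arrays, and Xist, which is expressed from an inactive X chromosome, was low (3.88 to 4.29). These values argue against livers of dams, and against female as the sex of the sampled animals. The submitters number the arrays, and 4 of the 5 arrays at 50 mg/kg stand among the 7 early arrays (numbers 1 to 8), each other group having 1 array there and the rest among the 12 late arrays (numbers 9 to 20). The question was which liver transcripts differ from vehicle at each dose.

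At 50 mg/kg Cyp1a1 and Cyp1a2, enzymes of the aryl hydrocarbon receptor (AhR) response, rose most. Cyp1a1, a monooxygenase of aromatic hydrocarbons, went from 7.69 ± 0.491 to 14.20 ± 0.078 (mean log2 ± SD, n = 5 each), a 91.3-fold rise (log2 fold change 6.51, SE 0.864, adjusted p = 0.00123). Here as elsewhere the SE takes in the spread of all dose groups. In Cyp1a1 the library labelled 0.1 mg/kg replicate 1 read 14.06 (others of its group 7.19 to 8.42). Cyp1a2, which also oxidises aromatic amines, rose 53.8-fold (log2 fold change 5.75, SE 0.879, adjusted p = 0.00345), a call that ended with tissue scores as covariates (adjusted p = 0.0608; 1.9e-06 to 0.0608 over all alternatives). Nqo1, a quinone reductase, rose 7.19-fold (2.85, SE 0.368, adjusted p = 0.00123). In each of these genes all 5 treated arrays lay above all 5 vehicle arrays. Cyp1b1 rose 9.06-fold with a wide spread (3.18, SE 0.766, adjusted p = 0.0442), and it passed in only 2 of the 10 fits that left out 1 array, those without 50 mg/kg replicate 2 or 4. Without 50 mg/kg replicate 1, 3 or 5 its adjusted p was 0.131, 0.0947 and 0.0795, and without vehicle replicates 1 to 5 it was 0.0696, 0.0584, 0.0707, 0.0842 and 0.109. Over all alternatives it ran from 0.0182 to 0.247. For Cyp1a1 it ran from 1.67e-10 to 0.0375 and passed in all 25. Of 8 measured AhR targets, 5 rose, 0 fell and 3 did not pass (5 adjusted over the list alone). The list stood higher than other genes (camera adjusted p = 3.25e-07; adjusted p = 0.272 with an estimated correlation).

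**Figure D1:**
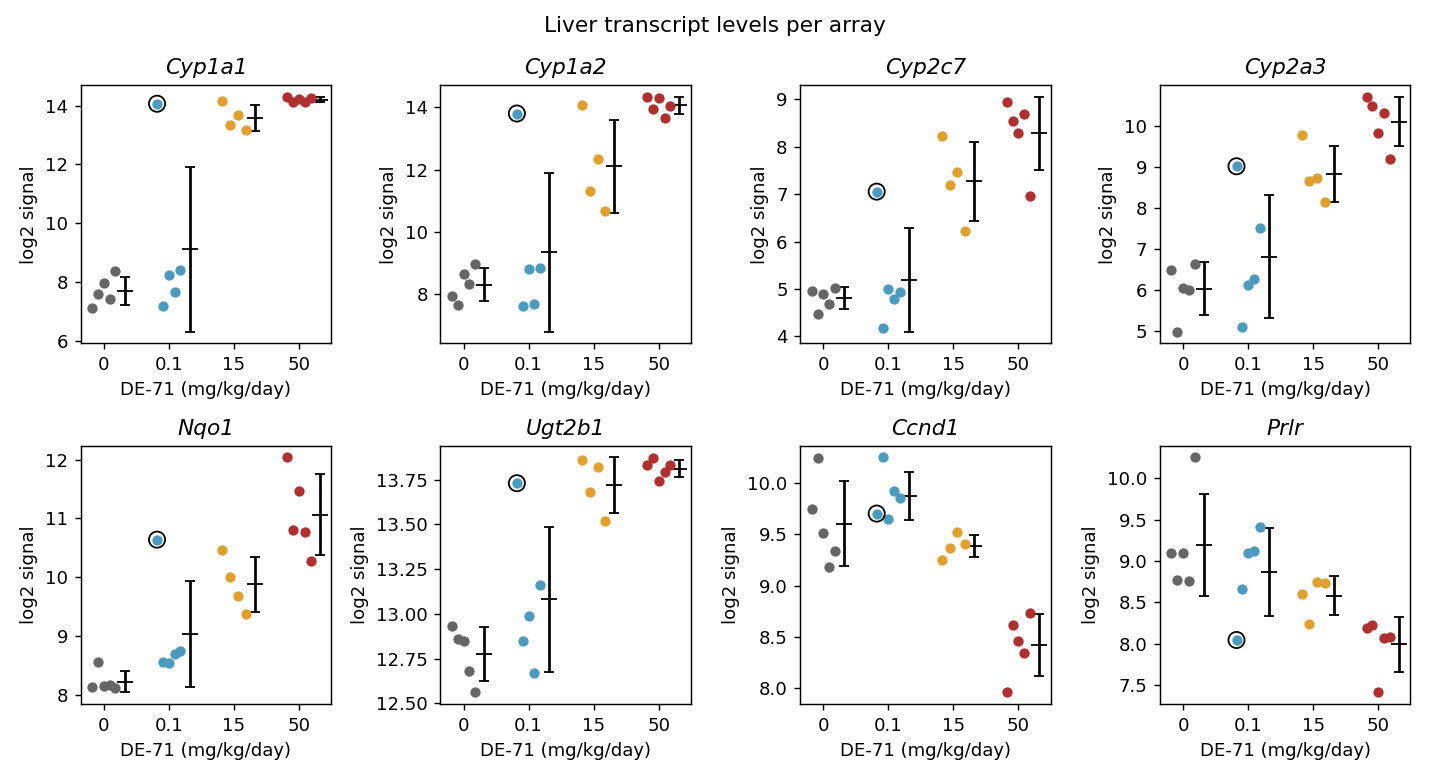
Log2 signal of 8 transcripts on each array against the dose of DE-71 in mg/kg per day, with the mean ± SD of each group beside its points; the ring marks the library labelled 0.1 mg/kg replicate 1. Cyp1a1 lay between 14.11 and 14.30 at 50 mg/kg and between 7.10 and 8.36 in vehicle.

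Targets of the constitutive androstane and pregnane X receptors (CAR and PXR), which sense drugs and other foreign compounds, rose as well. The cytochromes P450 Cyp2c7 and Cyp2c6v1 rose 11.2-fold (3.48, SE 0.462, adjusted p = 0.00123) and 4.89-fold (2.29, SE 0.367, adjusted p = 0.00428). With early and late arrays as a block Cyp2c7 kept its call (adjusted p = 0.00977) and Cyp2c6v1 did not (adjusted p = 0.053, and 2.12e-05 to 0.053 over all alternatives). Cyp2c6v1 passed in 24 of 25 alternatives, among them the block without the 3 doubted arrays. The efflux transporter Abcc3 (1.91, SE 0.299, adjusted p = 0.00369) and the carboxylesterase Ces2c (1.75, SE 0.237, adjusted p = 0.00123) rose 3.76-fold and 3.37-fold, and Abcc3 did not pass with tissue scores (adjusted p = 0.0546; 0.000148 to 0.0546 over all alternatives). Within the Cyp3a family, Cyp3a23-3a1 rose 1.78-fold (0.83, SE 0.102, adjusted p = 0.00123), while Cyp3a2 (0.14, adjusted p = 0.202) and Cyp3a18 (0.28, adjusted p = 0.765) did not pass. Cyp3a9 rose from a low level (0.60, adjusted p = 0.0147), a call that ended without 50 mg/kg replicate 1 (adjusted p = 0.0518; 0.00711 to 0.155 over all alternatives). Of 20 measured members, 13 rose, 0 fell and 7 did not pass (15 higher adjusted over the list alone), and the list stood higher (camera adjusted p = 2.77e-16; adjusted p = 0.252 with an estimated correlation). A probe set annotated to more than 1 gene rose as well (2.01, SE 0.273, adjusted p = 0.00123). Outside the lists, Cyp2a3 rose 16.9-fold (4.08, SE 0.553, adjusted p = 0.00123).

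Some enzymes and pumps that conjugate and export xenobiotics and bilirubin rose, and most did not pass. The glucuronosyltransferases Ugt2b10 (1.96, SE 0.341), Ugt2b15 (1.04, SE 0.147) and Ugt2b1 (1.04, SE 0.142) rose, with adjusted p = 0.00775, 0.00173 and 0.00131. With the early and late block Ugt2b15 (adjusted p = 0.00977) and Ugt2b1 (adjusted p = 0.016) kept their calls and Ugt2b10 lost its own (adjusted p = 0.0752, and 0.000137 to 0.0752 over all alternatives). Ugt2b10 passed in 24 of 25 alternatives, among them the block without the 3 doubted arrays. The sulfotransferase Sult1b1 did not pass (1.03, SE 0.313, adjusted p = 0.108). Of 18 phase II enzymes 5 rose, 0 fell and 13 did not pass (9 higher and 1 lower adjusted over the list alone), with camera adjusted p = 8.22e-05 (adjusted p = 0.437 with an estimated correlation). Of 23 hepatic transporters 3 rose, among them Abcc3 and Abcc2, the canalicular pump for conjugates (1.23, SE 0.167, adjusted p = 0.00123), and 20 did not pass (4 higher and 1 lower adjusted over the list alone). As a list the transporters did not pass (camera adjusted p = 0.183).

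Genes of the oxidative stress regulator NRF2 and of glutathione metabolism followed. Besides Nqo1, the glutathione transferase Gstm1 (1.29, SE 0.22, adjusted p = 0.00697) and malic enzyme Me1 (1.22, SE 0.179, adjusted p = 0.00249), which makes NADPH, rose 2.44-fold and 2.33-fold. Gstm1 lost its call with the early and late block (adjusted p = 0.0663) and with tissue scores (adjusted p = 0.101, and 0.000395 to 0.101 over all alternatives). It passed in 23 of 25 alternatives, among them the block without the 3 doubted arrays. Me1 lost its call with tissue scores (adjusted p = 0.0608, and 0.000436 to 0.0608 over all alternatives). Of 27 measured members 11 rose, 0 fell and 16 did not pass (15 higher and 1 lower adjusted over the list alone). The list stood higher (camera adjusted p = 1.16e-11; adjusted p = 0.252 with an estimated correlation). A glutathione transferase outside the list, Gstp3, fell 2.64-fold (-1.40, SE 0.268, adjusted p = 0.0132). Its adjusted p was 0.0968 with the block and 0.0733 with tissue scores, so both ended the call (0.0045 to 0.0968 over all alternatives). Gstp3 passed in 23 of 25 alternatives, among them the block without the 3 doubted arrays.

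Smaller rises were seen in interferon-induced and chaperone genes. Usp18, which removes ISG15 from proteins, rose 2.37-fold (1.24, SE 0.215, adjusted p = 0.00721), but did not pass with early and late arrays as a block (adjusted p = 0.0752) or with tissue scores (adjusted p = 0.0608; 0.00311 to 0.0752 over all alternatives). The ubiquitin-like Isg15 itself rose 1.98-fold (0.99, SE 0.236, adjusted p = 0.0423) but kept its call in only 1 of the 10 fits that left out 1 array, that without 50 mg/kg replicate 5, with adjusted p up to 0.11 in the others and 0.0238 to 0.241 over all alternatives. Of 30 interferon response genes 4 rose, 0 fell and 26 did not pass (15 higher adjusted over the list alone; camera adjusted p = 1.67e-07, and adjusted p = 0.515 with an estimated correlation). Among 24 genes of the unfolded protein response 4 rose, 0 fell and 20 did not pass (10 higher adjusted over the list alone). The largest of these was the chaperone cofactor Sdf2l1 (1.00, SE 0.201, adjusted p = 0.0184), whose adjusted p was 0.052 without vehicle replicate 1 and 0.00612 to 0.0795 over all alternatives. Chac1, induced through ATF4, did not pass (-1.23, adjusted p = 0.302). That list stood higher (camera adjusted p = 0.00109; adjusted p = 0.640 with an estimated correlation). Among 22 acute phase genes C-reactive protein (Crp) rose 2.97-fold (1.57, SE 0.252, adjusted p = 0.00428), and 21 did not pass, including Orm1 (1.35, adjusted p = 0.0675). The call of Crp ended with the block (1.36, adjusted p = 0.053) and with tissue scores (adjusted p = 0.0701, and 0.00063 to 0.0701 over all alternatives). Crp passed in 23 of 25 alternatives, among them the block without the 3 doubted arrays. Adjusted over the list alone 6 were higher (camera adjusted p = 0.00163; adjusted p = 0.708 with an estimated correlation).

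Fewer genes fell. Cyclin D1 (Ccnd1), which drives entry into the cell cycle, fell 2.27-fold on the representative probe set (-1.18, SE 0.176, adjusted p = 0.00258), and all 3 of its probe sets passed. The junction protein Amotl1 (-1.23, SE 0.192, adjusted p = 0.00363) and the liver pyruvate kinase Pklr (-0.91, SE 0.161, adjusted p = 0.0085) fell 2.35-fold and 1.88-fold. With early and late arrays as a block Ccnd1 and Amotl1 passed (adjusted p = 0.0345 and 0.0396) and Pklr did not (-0.78, adjusted p = 0.0821, and 0.0026 to 0.0821 over all alternatives). Pklr passed in 24 of 25 alternatives, among them the block without the 3 doubted arrays. The prolactin receptor (Prlr) fell 2.29-fold (-1.20, SE 0.272, adjusted p = 0.0342). It kept its call in 3 of the 10 fits that left out 1 array, those without vehicle replicate 2, 3 or 4, and reached an adjusted p of 0.0793 in the others (0.014 to 0.19 over all alternatives). The leptin receptor (Lepr) fell on 1 of 7 probe sets (-1.67, SE 0.344, adjusted p = 0.021), with 1 other of opposite sign, and did not pass without 50 mg/kg replicate 1 (adjusted p = 0.0623) or vehicle replicate 1 (adjusted p = 0.0542; 0.00683 to 0.126 over all alternatives). Of 17 genes of growth hormone and prolactin signalling 2 fell, Prlr and the carrier Igfbp2 (-0.54, SE 0.111, adjusted p = 0.0207), 0 rose and 15 did not pass (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00575, and adjusted p = 0.503 with an estimated correlation). Igfbp2 did not pass without 50 mg/kg replicate 1 or 4 or vehicle replicate 4 or 5 (adjusted p = 0.0622, 0.0605, 0.0565 and 0.057; 0.00711 to 0.165 over all alternatives).

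**Figure D2:**
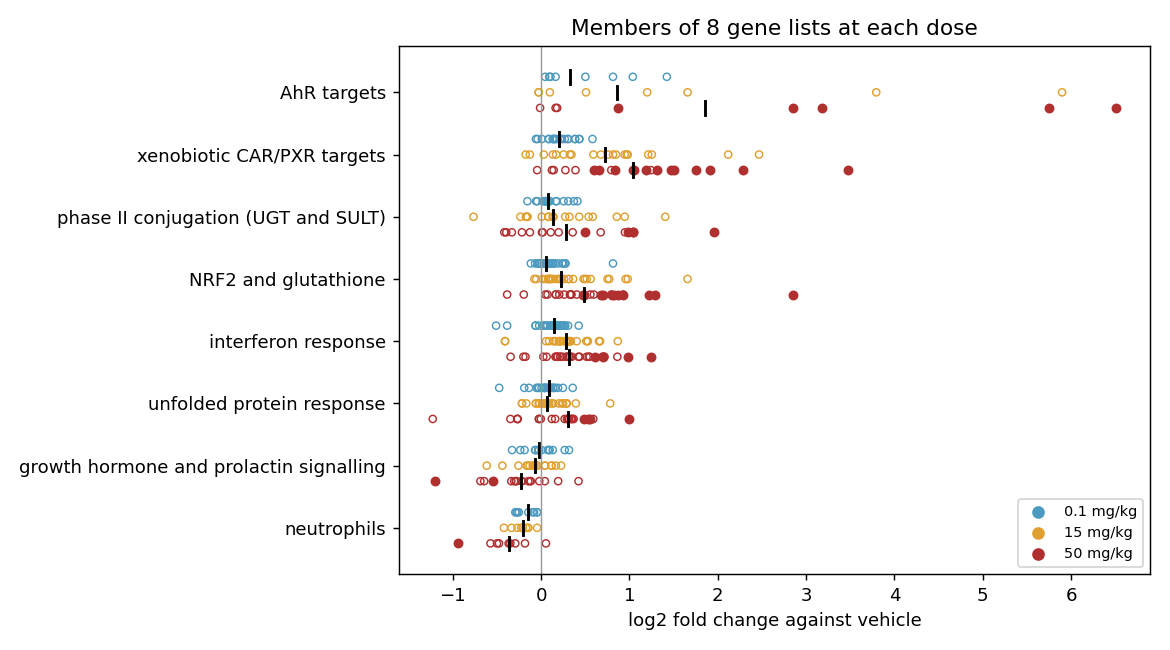
Log2 fold change against vehicle of each measured member of 8 gene lists at 0.1, 15 and 50 mg/kg, filled where the adjusted p was under 0.05, with a black bar at the list's median. At 50 mg/kg the median was 1.86 for AhR targets, 1.04 for CAR and PXR targets and -0.37 for neutrophil transcripts.

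Other metabolic lists held few changes at 50 mg/kg. Lipogenesis had 2 genes higher, Me1 among them, and 1 lower, Pklr, of 23 (6 higher and 1 lower adjusted over the list alone), and stood higher (camera adjusted p = 0.0399; adjusted p = 0.759 with an estimated correlation). With early and late arrays as a block that list did not pass (median 0.05, adjusted p = 0.292; 0.00592 to 0.759 over all alternatives). Of 21 genes that differ between male and female rat liver 3 rose and 1 fell (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0126, and adjusted p = 0.708 with an estimated correlation), a list call that the block ended (median 0.14, adjusted p = 0.105; 0.00562 to 0.708 over all alternatives). The steroid reductase Akr1c14 was among those that rose (0.86, SE 0.164, adjusted p = 0.0132). It lost its call with the early and late block (adjusted p = 0.0942) and with tissue scores (adjusted p = 0.0931, and 0.00208 to 0.0942 over all alternatives). It passed in 23 of 25 alternatives, among them the block without the 3 doubted arrays. Bile acid synthesis had 0 of 17 genes past limma's threshold, and 0 adjusted over the list alone, with Cyp7a1, its rate-limiting enzyme, at 0.52 (SE 0.439, adjusted p = 0.599). Of 18 genes of thyroid hormone metabolism and response, Me1 rose and 17 did not pass (3 higher and 2 lower adjusted over the list alone), among them the deiodinase Dio1 (-0.50, adjusted p = 0.384) and thyroxine-binding globulin Serpina7 (-0.62, adjusted p = 0.117). Transthyretin (Ttr), which carries thyroxine, stood at -0.10 (adjusted p = 0.307), and Afp at -0.06 (adjusted p = 0.582). Both lay close to the top of the signal range (14.53 and 14.62 in vehicle), where a fold can read too low. Of 34 cell cycle genes only Ccnd1 passed, and of 28 PPAR alpha targets 1 rose and 1 fell, the same counts as adjusted over the list alone. Camera gave adjusted p = 0.763, 0.752, 0.596 and 0.681 for these lists.

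Transcripts of other cells and tissues also differed in level. Neutrophil transcripts stood lower at 50 mg/kg (median -0.37; camera adjusted p = 0.00061, and adjusted p = 0.708 with an estimated correlation). The early vehicle array (9.86) lay within the range of the 4 early 50 mg/kg arrays (9.82 to 10.43), while among late arrays the 50 mg/kg one (9.93) lay below vehicle (10.64 to 10.76), so with 1 array in an arm of each part the direction was not settled. With early and late arrays as a block the median was -0.13 (adjusted p = 0.0248; 8.91e-08 to 0.708 over all alternatives), and within the early arrays Camp stood at 0.06. Of 9 members 1 fell, the antimicrobial peptide gene Camp (-0.94, adjusted p = 0.0457), and 8 did not pass (4 lower adjusted over the list alone). Camp passed in only 1 of the 10 fits that left out 1 array, that without vehicle replicate 1, and reached an adjusted p of 0.112 in the others (0.00512 to 0.245 over all alternatives). Lists of stellate cell, exocrine pancreas and bile duct transcripts stood lower with 0 members past limma's threshold and 0 adjusted over the list alone (camera adjusted p = 0.00379, 0.0122 and 0.0183; adjusted p = 0.759, 0.849 and 0.829 with an estimated correlation). With the block the pancreas (median -0.65, adjusted p = 0.0772; 0.00139 to 0.934 over all alternatives) and bile duct lists (median -0.28, adjusted p = 0.103; 0.00208 to 0.829 over all alternatives) did not pass. Single arrays carried these transcripts. The mean log2 level of the pancreas list was 8.53 in vehicle replicate 2 and 7.23 in vehicle replicate 4 against a median of 4.94 over the 19 arrays. That of the skeletal muscle list was 10.77 in vehicle replicate 1, 8.93 in vehicle replicate 5 and 9.46 and 9.07 in 50 mg/kg replicates 2 and 3, against a median of 5.38.

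**Figure D3:**
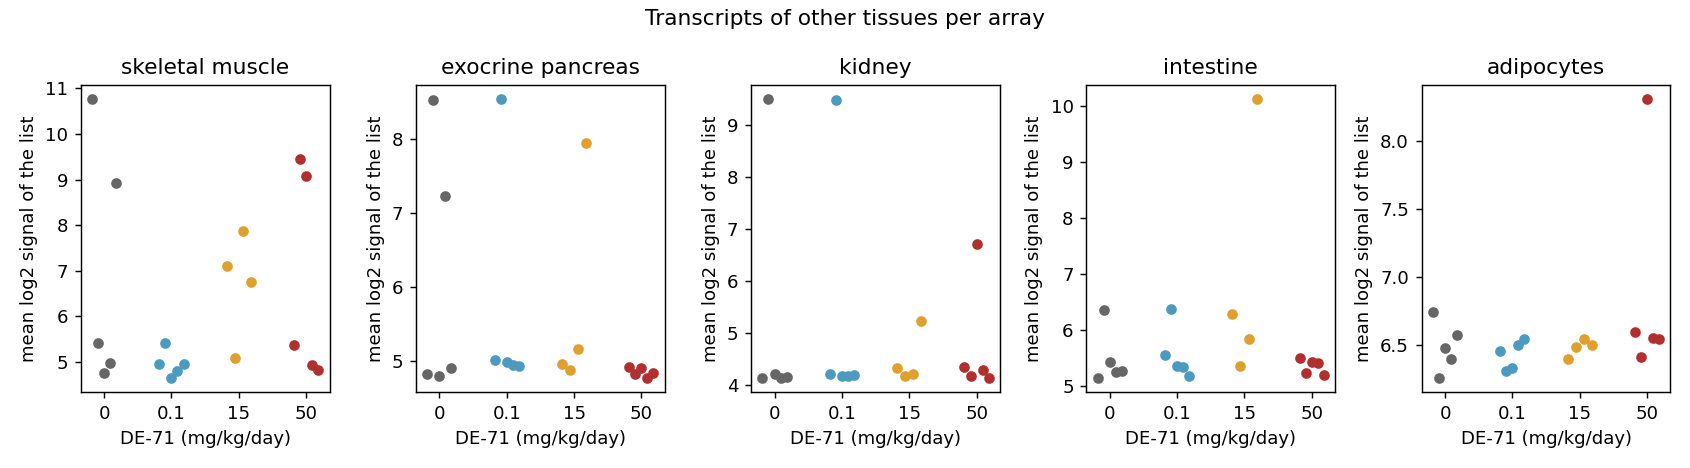
Mean log2 signal of lists of skeletal muscle, exocrine pancreas, kidney, intestine and adipocyte transcripts on each array against the dose of DE-71 in mg/kg per day, with 1 point per array. The kidney list reached 9.51 and 9.48 on vehicle replicate 2 and 0.1 mg/kg replicate 2 against a median of 4.21, and the intestine list 10.12 on 15 mg/kg replicate 5.

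In total 499 of 31042 probe sets passed at 50 mg/kg, 380 higher and 119 lower, which named 294 and 82 genes. Of these probe sets 157 rose and 52 fell by over 1.5-fold. Among all 14217 genes, passed or not, the groups did not overlap in 618 that stood higher and 211 that stood lower, where chance gives 0.397% of genes, or 56.4, per direction. With early and late arrays as a block 57 passed, 56 of them among the 499, at fold changes of 0.905 times the unblocked ones and SEs of 1.13 times (medians). Cyp1a1, Cyp2c7, Nqo1 and Ccnd1 were among those 57. The same block without the 3 doubted arrays gave 216, 170 of them among the 499. Within the early arrays 498 of the 499 kept their sign and within the late arrays 499, but they were picked on these same arrays and each part has 1 array in one arm, so this tests little. With scores of 4 other tissues as covariates 78 passed, 75 of them shared. Leaving out 1 array changed the count to 178, 301, 330 and 230 (50 mg/kg replicates 1, 2, 3 and 4) and 237, 253, 259 and 222 (vehicle replicates 1, 2, 4 and 5). Of 46 genes named at this dose, 24 passed in each of the 10 fits that left out a vehicle or 50 mg/kg array. With the early and late block 15 passed, and with tissue scores 15. In all of these fits 11 passed: Cyp1a1, Cyp2a3, Cyp2c7, Cyp3a23-3a1, Nqo1, Ugt2b1, Ugt2b15, Abcc2, Ces2c, Amotl1 and Ccnd1.

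At 15 mg/kg Cyp1a1 averaged 13.59 ± 0.442 (n = 4) against 7.69 ± 0.491 in vehicle, and each of the 4 arrays (13.16 to 14.17) lay above each vehicle array. Its log2 fold change of 5.90 (SE 0.917) had an adjusted p of 0.0724 over all probe sets. The same adjusted p was reached by Ugt2b1 (0.95, SE 0.151), Cyp3a23-3a1 (0.68, SE 0.109) and the probe set annotated to more than 1 gene (1.77, SE 0.289). Cyp1a2 (3.80, SE 0.932), Cyp2c7 (2.47, SE 0.49), Cyp2c6v1 (2.12, SE 0.389) and Nqo1 (1.66, SE 0.39) had adjusted p of 0.419, 0.199, 0.165 and 0.366. With limma 0 probe sets passed, while 3083 had an unadjusted p under 0.05 against 1552 by chance. An ordinary t without shrinkage and a prior with trend also gave 0.

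The spread used at 15 mg/kg takes in all groups, and the library labelled 0.1 mg/kg replicate 1 lay far from the others of its group in Cyp1a1 (14.06 against 7.19 to 8.42). Without that library 11 probe sets passed at 15 mg/kg, all higher. They were those of Cyp1a1 (adjusted p = 2.18e-09), Cyp1a2, Cyp2a3, Cyp2c7, Cyp2c6v1, Nqo1, Ugt2b1, Ugt2b15, Cyp3a23-3a1, Mmgt1 and the probe set annotated to more than 1 gene, of which Mmgt1 was named after its value was seen. Over 24 alternative fits the adjusted p of Cyp1a1 at 15 mg/kg ran from 2.18e-09 to 0.546 and lay under 0.05 in 8. With early and late arrays as a block 7 probe sets passed at 15 mg/kg, all higher.

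Adjusted over the list alone at 15 mg/kg, 14 of 20 CAR and PXR targets, 4 of 8 AhR targets and 5 of 18 phase II enzymes were higher, and 0 of each over all probe sets. Camera placed these lists higher (adjusted p = 8.71e-14, 0.000125 and 0.000263; adjusted p = 0.252, 0.503 and 0.503 with an estimated correlation). The interferon and NRF2 lists stood higher, with medians of 0.29 and 0.23 and 1 member each adjusted over the list alone (adjusted p = 4.49e-07 and 4.54e-06; adjusted p = 0.555 and 0.503 with an estimated correlation). Lymphocyte, sex-biased, cholesterol synthesis and unfolded protein response lists also stood higher (adjusted p = 0.00061, 0.00768, 0.0122 and 0.0416), and stellate cell and neutrophil lists lower (adjusted p = 0.0294 and 0.0355), with 0 members past the threshold in each, also adjusted over the list alone. With an estimated correlation the adjusted p of these 6 lists was 0.503, 0.640, 0.917, 0.829, 0.890 and 0.849. The unfolded protein response list did not pass with early and late arrays as a block (camera adjusted p = 0.0505, and 0.00244 to 0.829 over all alternatives).

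At 0.1 mg/kg no transcript passed. The smallest unadjusted p-values belonged to the cytokine Il10 (0.35, SE 0.0899), the chromatin protein Hmga2 (0.27, SE 0.0762) and the semaphorin co-receptor Plxna4 (-0.30, SE 0.0849), all with an adjusted p of 1. With limma 0 probe sets passed and 763 had an unadjusted p under 0.05, where 1552 are expected by chance. An ordinary t and a prior with trend gave 0 too. Over the other 4 libraries of this dose Cyp1a1 differed from vehicle by 0.19 (95% interval -0.371 to 0.745) and Ugt2b1 by 0.15 (95% interval -0.0648 to 0.357). Nqo1 stood at 0.41 in those 4 (95% interval -0.165 to 0.994). Of 9 genes looked at in this way only Ugt2b15 had an interval without 0 (0.32, 95% interval 0.0122 to 0.617), and its adjusted p with limma was 1. Of the 4 libraries, 0.1 mg/kg replicate 2 was nearly identical to vehicle replicate 2. Without that pair as well (3 against 4 arrays) Cyp1a1 stood at 0.39 (95% interval -0.2 to 0.972), Nqo1 at 0.52 (95% interval -0.158 to 1.21) and Ugt2b15 at 0.36 (95% interval -0.00287 to 0.721). The interval was -1.26 to 1.19 for Cyp1a2 and -0.88 to 0.918 for Cyp2c7. Differences within these intervals are not excluded at this dose. The 3 Nqo1 values (8.55 to 8.75) lay above those of the 4 vehicle arrays (8.12 to 8.16). Vehicle replicate 2, left out here, read 8.55, so this separation depends on leaving it out. The library labelled 0.1 mg/kg replicate 1 stood apart, with Cyp1a2 at 13.80 against 7.63 to 8.83 and Nqo1 at 10.64 against 8.55 to 8.75.

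**Figure D4:**
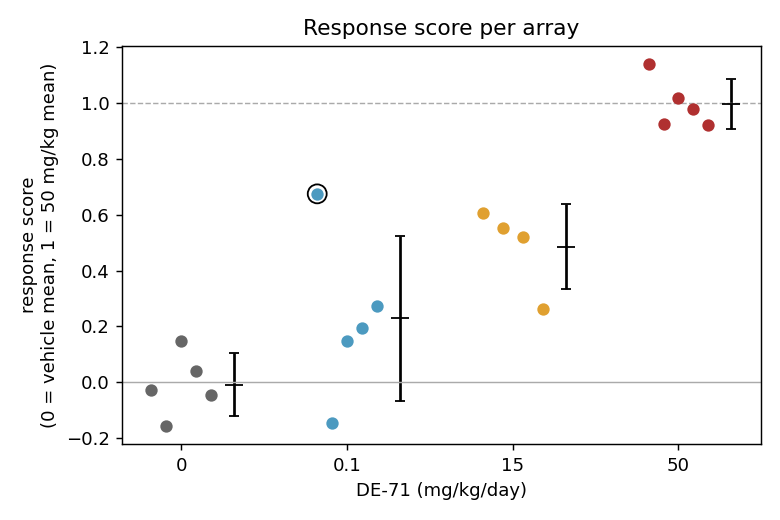
Response score of each array against the dose of DE-71 in mg/kg per day, with the mean ± SD of each group. On its scale 0 is the vehicle mean and 1 the 50 mg/kg mean. It was taken over 376 probe sets that passed in a fit of the vehicle and 50 mg/kg arrays alone. The ring marks the library labelled 0.1 mg/kg replicate 1 at 0.675, above the 15 mg/kg arrays (0.264 to 0.605). The other 0.1 mg/kg arrays lay between -0.144 and 0.273, and vehicle between -0.157 and 0.148. The probe sets were picked on these vehicle arrays, so arrays of other groups can score above 0 without a change.

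Camera called 8 lists at 0.1 mg/kg. Skeletal muscle transcripts (median -2.31), stellate cell transcripts (-0.40) and neutrophil transcripts (-0.14) stood lower (adjusted p = 9.77e-09, 4.49e-07 and 0.00556; adjusted p = 0.503, 0.503 and 0.737 with an estimated correlation). The muscle list averaged 10.77 in vehicle replicate 1 and 8.93 in vehicle replicate 5. CAR and PXR, AhR, interferon, NRF2 and phase II lists stood higher (adjusted p = 0.00228, 0.00988, 0.0303, 0.0399 and 0.0469; adjusted p = 0.737, 0.708, 0.917, 0.849 and 0.737 with an estimated correlation). In these 8 lists 0 members passed, also adjusted over the list alone, whereas Hmga2 passed adjusted over the list alone among fetal and neonatal liver markers (adjusted p = 0.0376 in that list). The count of 8 lists fell to 2, both lower, without the library labelled 0.1 mg/kg replicate 1, so that none of the 5 higher lists kept its call, and to 5 without vehicle replicate 3 or vehicle replicate 4.

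Between 50 and 15 mg/kg the largest shifts by p were in the bicarbonate transporter Slc4a4 (0.74, SE 0.118), Mgarp, a mitochondrial protein (1.10, SE 0.178), and Tnfaip8l1 (0.88, SE 0.143), each with an adjusted p of 0.0787. Against vehicle these genes rose at 50 mg/kg (0.82, 1.30 and 1.15; adjusted p = 0.00123, 0.00123 and 0.000893) and stood at 0.08, 0.20 and 0.28 at 15 mg/kg. Ccnd1 was lower at 50 than at 15 mg/kg by -0.97 (SE 0.186, adjusted p = 0.189), and Cyp1a1 differed by 0.61 (SE 0.917, adjusted p = 0.94). With limma 0 probe sets passed and 2417 had an unadjusted p under 0.05. An ordinary t and a prior with trend gave 0 as well. Without vehicle replicate 2 and 0.1 mg/kg replicate 2, which were nearly identical, 2 probe sets passed, both of Ccnd1 and both lower. With the library labelled 0.1 mg/kg replicate 1 left out as well, 0 passed.

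Of the 499 probe sets called at 50 mg/kg, 493 had the same sign at 15 mg/kg (98.8%), at a median of 0.469 times the change. Both comparisons use the same vehicle arrays, and unchanged groups simulated against them gave a median of 80.5% of the same sign and 100% at most. With the vehicle arrays split, 3 for the calls and 2 for the change at 15 mg/kg, the share was 65.1% to 97.1% over 10 splits, and the median ratio 0.138 to 0.587. The covariance of the fold changes was 0.033 against a simulated median of 0.0137, a difference of 0.0192, but simulations reached 0.11, and split vehicle arrays gave -0.00696 to 0.0201. Over all probe sets 0 were called at both doses. At an unadjusted p under 0.05, 741 were higher at both doses and 426 lower. Independent lists would share 196 and 60.4, which leaves out the shared vehicle arrays. Unchanged groups with a shared control group, simulated from residuals of all arrays, gave a median of 82 and 115.5 and up to 1928 and 1328 in 100 simulations. Since these residuals include that library too, the simulations do not decide the question, and no shared change is read from the overlap. Without the library labelled 0.1 mg/kg replicate 1 all 11 probe sets called at 15 mg/kg, Cyp1a1 and Cyp2c7 among them, were also called at 50 mg/kg. Independent lists would share 0.161, which again leaves out the shared arrays, and simulated unchanged groups shared 0. Unchanged groups seldom pass the adjusted threshold at either dose, so that 0 was largely set beforehand and no conclusion is drawn from it.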

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

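The tests of the library labelled 0.1 mg/kg replicate 1, of the near-identical arrays and of other tissue at 50 mg/kg were chosen only after the result was seen. Among 160 groups of arrays tested over 40 measures, 26 held an array far from the rest, where chance alone picks out about 1 in 20 groups, or 8.

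The library labelled 0.1 mg/kg replicate 1 stood apart in 7 measures. It had Cyp1a1 at 14.06, Cyp1a2 at 13.80, Cyp2c7 at 7.06, Nqo1 at 10.64, Poteml2 at 8.24 and Dnajb3 at 7.22, all above the other 4 libraries of the dose, and eosinophil transcripts at 5.65 (others 6.91 to 7.15), the last a value shared by the 6 other early arrays (5.48 to 6.51) and so not particular to it. An exchange with a 15 or 50 mg/kg library is argued against, since the lowest Cyp1a1 value among those libraries was 13.16, above the highest vehicle value of 8.36. Other tissue in it is argued against too, since none of 5 tissue scores exceeded the median of the 19 libraries by more than 0.132. A wrong label or an exchange with a sample outside the series cannot be told apart from a stronger response of this animal: its response score was 0.675, its description alone holds a further 2 after the replicate number, and no 15 mg/kg replicate 1 and no array number 7 are among the samples, but no value here separates them.

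Vehicle replicate 2 and 0.1 mg/kg replicate 2 were nearly identical, with r = 0.9986 over probe sets (next highest of 171 pairs 0.9966). Kidney transcripts averaged 9.51 and 9.48 in them (others 4.14 to 4.21 in each group), bile duct transcripts 8.165 in both, pancreas transcripts 8.53 and 8.55, and intestine transcripts 6.36 and 6.38. Over the 1000 probe sets that vary most among the other 17 arrays, the SD of their differences was 0.157 (next pair 0.486), which is consistent with RNA of 1 animal on both arrays. Kidney and pancreas tissue alone is argued against, as without the probe sets higher in both arrays than in the other 17 the SD was 0.125 (next pair 0.198). No biological explanation was tested, and which of the 2 labels would hold stays open.

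The arrays at 50 mg/kg are mostly numbered 1 to 8, and an unexplained number in the descriptions begins with 1 or 2 on these and with 3 or 4 on the others, so that a cohort or necropsy day, if it marks one, goes with the array number. For higher probe sets, 24 called from the 4 early arrays kept a median of 0.731 of their change in the late 50 mg/kg array against other vehicle arrays (0.1 mg/kg arrays in its place gave -0.00455 to 0.144), and for lower ones 0.365 over 30 probe sets (0.0159 to 0.0612). With 1 late array these ratios exclude nothing, so array order and dose cannot be told apart by them; with early and late arrays as a block the fold changes were 0.905 times as large (median) and 57 probe sets passed. With scores of skeletal muscle, pancreas, kidney and intestine as covariates the fold changes were 0.898 times as large (median). All 499 kept their sign, but they were picked on these same arrays, so the signs test little. Only 78 passed, 75 of them among the 499. For these 75 the fit argues against the tissues scored as the whole cause, and other tissues were not covered. How far smaller folds, SEs 1.13 times as large and fewer degrees of freedom each lowered the count was not separated. The 57 probe sets that passed with the early and late block argue against a shift between early and late arrays as their whole cause. Cyp1a1 was among them. On late arrays it read 13.16 to 13.68 in the 15 mg/kg libraries and 7.43 to 8.36 in vehicle. The block fit of all arrays holds the library labelled 0.1 mg/kg replicate 1, an early array with Cyp1a1 at 14.06. Its early term can therefore take up part of a response. With the block and without the 3 doubted arrays, 216 probe sets passed, 170 of them among the 499, at 0.935 times the fold changes (median). For those of the 499 that passed in neither block fit, array order and dose were not told apart. A response to the dose stays open for them as a hypothesis.

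Exchanging arrays between the groups, over 100 splits for each result, was used to ask whether chance can be excluded. For the 499 probe sets at 50 mg/kg only the real split gave as many (1 of 100 run, of 126 possible). This argues against chance for that count, but it takes the arrays as independent samples, which the labels do not say. The highest other split gave 226. That split exchanged 50 mg/kg replicates 3 and 4 with vehicle replicates 1 and 2, and the split of early from late arrays gave 0. For the counts of 0 at 0.1 mg/kg, 15 mg/kg, between 50 and 15 mg/kg and at both doses, 100 of 100 splits gave as many, which a count of 0 fixes in advance, so that this tests nothing; the highest others were 3, 1, 3 and 0. For the list counts chance cannot be excluded. At 0.1 mg/kg 66 splits gave at least the real 8 lists (highest 18), at 15 mg/kg 22 gave at least 11 (highest 16), and at 50 mg/kg 14 gave at least 14 (highest 17).

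In other groups, neutrophil transcripts were low in vehicle replicate 1 (9.86; others 10.64 to 10.76). In 50 mg/kg replicate 3 adipocyte (8.31; others 6.41 to 6.60), kidney (6.72; others 4.15 to 4.36) and bile duct transcripts (6.85; others 6.35 to 6.48) were high and Prlr was low (7.41; others 8.07 to 8.23). In 15 mg/kg replicate 5 pancreas (7.95; others 4.88 to 5.16) and kidney transcripts (5.25; others 4.18 to 4.34) were high. In 15 mg/kg replicate 2 hepatocyte transcripts (13.74; others 13.78) and Prtg (4.43; others 5.34 to 5.48) were low. Nqo1 was high in vehicle replicate 2 (8.55; others 8.12 to 8.16), Prlr in vehicle replicate 5 (10.25; others 8.76 to 9.09) and Mmp14 in 0.1 mg/kg replicate 2 (10.39; others 9.27 to 9.53). Tsku was low in 15 mg/kg replicate 3 (9.55; others 10.04 to 10.07).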

How the results depend on the processing

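The fits without the doubted arrays, with tissue scores and with early and late arrays as a block were chosen after the data had been seen; the cause of the differences was not tested unless said. The count of 0 at 0.1 mg/kg was the same in every alternative run. At 15 mg/kg (0) the count was 4 with only probe sets above the median level, where fewer were tested (Cyp1a1, Ugt2b1, Cyp3a23-3a1 and a probe set annotated to more than 1 gene), 2 with the compared groups alone (Cyp1a1 and that probe set), 8 with the array number as a covariate, 13 with array weights, 10 without the 3 doubted arrays, 7 with the early and late block and 14 with that block and without those arrays. Leaving out 1 array gave 0 to 11, the latter without the library labelled 0.1 mg/kg replicate 1. The count at both 15 and 50 mg/kg (0) was 4, 8, 10, 10, 7 and 14 under the same settings in that order, without the compared groups alone, and 0 to 11 leaving out 1 array.

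At 50 mg/kg (499) the count was 171 with the array number, 921 with array weights, 78 with tissue scores, 57 with the early and late block and 216 with that block without the 3 doubted arrays, and 178 to 593 leaving out 1 vehicle or 50 mg/kg array, or 616 without the library labelled 0.1 mg/kg replicate 1. All 499 kept their sign in these fits with all arrays. The other alternatives gave 376 (compared groups alone) to 691 (only probe sets above the median level). Between 50 and 15 mg/kg (0) the fit without the near-identical arrays gave 2, and that without the 3 doubted arrays gave 0. With an estimated correlation 0 lists passed at each dose. Lists at 0.1 mg/kg (8) were 5 without the 3 doubted arrays and 2 to 12 leaving out 1 array; those at 15 mg/kg (11) 9 to 14, and those at 50 mg/kg (14) 12 to 16. Lists at 15 mg/kg were 8 and at 50 mg/kg 10 with only probe sets above the median level, and at 50 mg/kg 11 with the early and late block (10 shared), 11 with that block without the 3 doubted arrays (8 shared) and 17 with array weights. At 0.1 mg/kg 2 list medians turned: NRF2 and glutathione to -0.0222 without the 3 doubted arrays (adjusted p = 0.923), and stellate cells and fibroblasts to 0.0172 with tissue scores (adjusted p = 0.934).

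Over all groups the replicate numbers do not pair the arrays: 11 of 27 same-numbered pairs had a correlation of deviations over 0.1 (-0.534 to 0.889). Of 19 arrays 6 matched their own number best. Between vehicle and 0.1 mg/kg the correlation was 0.889, 0.32, 0.359 and 0.261 for replicates 2 to 5, and 0.0478 for replicate 1. The near-identical replicate 2 of these groups moved both group means alike. Deviations of the other replicates can then correlate whatever their numbers. Pairs of different numbers were not set beside them, so no pairing is read from these values. With the replicate block 511 probe sets passed at 50 mg/kg, 363 higher and 148 lower, 409 of them shared with the 499. Signal over background was not measured here, and genes near the floor of the range, such as Cyp3a9 (3.71 in vehicle), have folds that read low.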

Other observations

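The kidney, intestine and eosinophil lists, the early and late comparison and the interval fits at 0.1 mg/kg were chosen only after the result was seen. Granule protein transcripts of eosinophils separated arrays by number. Prg2, eosinophil granule major basic protein, averaged 6.70 ± 1.09 (SD) on the 7 early arrays and 10.23 ± 0.595 on the 12 late ones, and Epx, eosinophil peroxidase, 5.38 ± 1.12 and 8.76 ± 0.544. In a fit with the dose groups as terms they were lower on early arrays by -3.72 and -3.54 (adjusted p = 0.00409 each), and 3 probe sets passed, all lower on early arrays. Without the 3 doubted arrays 0 passed with limma, and 2556 had an unadjusted p under 0.05. Other eosinophil transcripts did not separate in the same way: Alox15 averaged 10.76 ± 0.48 and 10.84 ± 0.407, and Ccr3 4.63 ± 0.179 and 4.55 ± 0.207.

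Transcripts of tissues next to the liver varied between single arrays of every group. Skeletal muscle transcripts ranged from 4.64 to 10.77 over the 19 arrays, exocrine pancreas from 4.77 to 8.55, kidney from 4.14 to 9.51, intestine from 5.14 to 10.12 and adipocytes from 6.26 to 8.31. Hepatocyte transcripts ranged from 13.55 to 13.87, high in the signal range where differences can read too low, and erythroid transcripts from 7.71 to 9.26. Albumin (Alb) averaged 15.04 ± 0.0108 and the haemoglobin chain Hbb 14.43 ± 0.125.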
